A study of Mus musculus with 18 samples.

How the data were processed

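The deposited values are TPM of 56876 genes in 18 libraries, given with 2 decimals, and every library adds up to the same total. Reads were trimmed with fastp, aligned to GRCm39 and quantified with RSEM, per the submitters' processing notes, which give no versions. TPM keep no sequencing depth, so the depth of the libraries is unknown and no count-based model was possible. Values were used as log2(TPM + 1). Of the genes, 2863 had no symbol. Genes were identified by symbol, or with the gene identifier where the symbol was missing or shared. Unannotated assembled transcripts without an Ensembl identifier made up 1462 of the rows, and 1241 of these were tested. No coordinates were used because the reference annotation is of an earlier build.

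The labels conflict. The titles separate T from N and the codes I, P and GC, but the treatment tag names anti-PD-1 for every T library and WT for every N library, and the cell-type tag calls all 18 libraries tumour-bearing. Groups follow the titles, and no group was reassigned from its values. The labels name no batch and no animal shared between groups, and replicate numbers are not repeated across groups.

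Genes with at least 1 TPM in at least 3 libraries were tested, 16635 in number. limma 3.58.1 in R 4.3.3 fitted 6 group means over the 18 libraries with an intensity trend in the prior variance, leaving 12 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes were called at an adjusted p of 0.05. The comparisons were tumour against WT within each code and averaged over codes, each pair of codes within each tumour state, and the interactions of code P and of code GC with the tumour. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The p-values given for lists are mostly those with the estimated correlation, and fry results are given only for some lists. Of 32 lists, 31 were tested, because only 2 of 24 pancreatic genes passed the filter. List members are also counted after adjustment over the list alone. The groups, comparisons, lists, filter, tests and all alternatives but 1 were chosen before the data were examined.

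Genes named in the text are the 10 with the largest rise and the 10 with the largest fall among genes called, with a mean of at least 5 TPM in the higher group, no overlap between the libraries of the groups and a symbol that is not a predicted gene, pseudogene or receptor segment. To these were added the members with the smallest p of each list in each direction and a set fixed beforehand that included Pdcd1, Cd274, Csf3, Csf3r, Arg1, S100a8, S100a9, Hbb-bs, Cd3e and Mki67. Where fewer than 5 genes passed, the 5 with the smallest p were considered. Not every gene that met the rule is described, and results of some genes withheld for evaluation are not reported.

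Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, TPM recomputed without haemoglobin, immunoglobulin, T cell receptor, ribosomal protein and mitochondrial genes, a fit of only the libraries of a comparison, array weights by tumour status, robust empirical Bayes moderation, omission of each library in turn and estimated correlations. Recomputation of TPM without the genes of the 3 neutrophil lists was added after the data had been seen. Libraries were also regrouped within each comparison to ask how many genes an arbitrary split calls.

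The procedure was tested on simulated data made for T_P against T_I, with 200 of 16635 genes changed in each of 5 simulations. These 200 were drawn from genes above a set mean expression, so recovery of weakly expressed genes was not assessed. The genes of the proliferation list were also shifted, by a smaller amount, and were left out of the false calls. Values were normal noise around a mean common to all groups, without the differences between the real groups. Genes changed by 1 log2 unit were recovered in 88.2% of cases and by 2 log2 units in 96.8%, with a mean of 27.4 false calls. The sum constraint of TPM caused part of these, as the mean was 11 without it. Other tools were statmod 1.5.0, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

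Left out were splicing, unannotated assembled transcripts (tested but not described), single genes of the immunoglobulin and T cell receptor repertoire, and deconvolution into cell fractions, for which no reference profile was at hand. Transcript abundances in whole splenocytes do not separate a change in cell numbers from a change within cells.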

Results

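RNA was sequenced from splenocytes of female Balb/c mice, some of which carried orthotopic tumours of 4T1, a mouse mammary carcinoma line that serves as a model of triple-negative breast cancer. Antibodies against G-CSF or PD-1, or control IgG, were injected on days 18, 21 and 24 after tumour implantation, and spleens were taken on day 29. G-CSF is the cytokine that drives granulocyte production, and PD-1 is an inhibitory receptor of T cells. The question is how the tumour and these antibodies alter the immune and blood-forming cells of the spleen. The 18 libraries form 6 groups of 3, T (tumour-bearing) or N (WT) combined with the codes I, P and GC. The design names 3 antibodies whose initials correspond to the codes, but no label expands a code, so groups are named by code throughout.

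S100a8 and S100a9, which encode the calprotectin subunits of neutrophils and monocytes, together took 14.7% ± 0.370 of all TPM in T_I and 14.8% ± 0.729 in T_P (mean ± SD, n = 3 in every group of this report). Their share was 3.64% ± 0.924 in T_GC, 0.366% ± 0.181 in N_I, 0.305% ± 0.0708 in N_P and 0.0569% ± 0.0285 in N_GC. The genes of 3 neutrophil lists together held 23.2% of TPM in T_I, 22.8% in T_P and 6.02% in T_GC. On the first principal component, which carried 64.8% of the variance, T_I and T_P libraries lay between 83.8 and 94.6, N libraries between −75.0 and −46.6, and T_GC libraries between −4.86 and 1.64. Pearson correlations between replicates ran from 0.953 to 0.976 over genes, which are not independent replicates. TPM values of a library add up to a fixed total, so the rise of a few very abundant genes lowers the rest. Scaling by median of ratios moved the median of all genes by 0.39 log2 units in T_I against N_I, 0.36 in T_P against N_P, −0.36 in T_GC against T_I and −0.35 in T_GC against T_P. Changes are therefore relative to the total, and the numbers of genes higher and lower under that scaling follow where they differ.

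**Figure D1:**
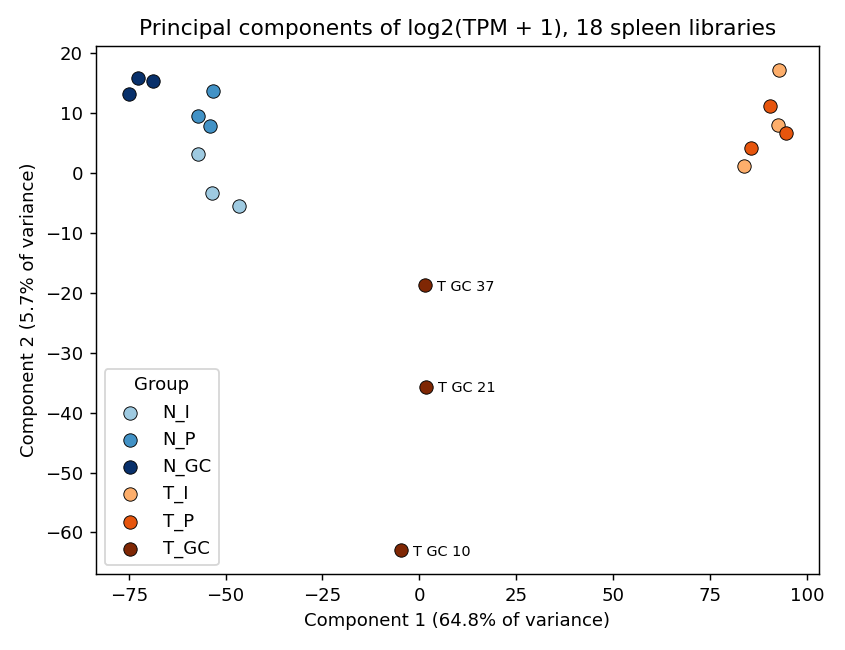
Scores of the 18 libraries on the first and second principal components of log2(TPM + 1), with 1 point per library coloured by group. T_I and T_P libraries lie together, N libraries lie together, and T_GC libraries lie between them on the first component.

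Neutrophil genes were among those with the largest differences between T_I and N_I spleens. S100a9 (ENSMUSG00000056071) rose from 2641 ± 1247 TPM in N_I to 101870 ± 3342 in T_I (log2 fold change 5.42, adjusted p = 7.82e-09). Prtn3, Elane and Ctsg, serine proteases packed into primary granules at the promyelocyte stage, rose by 7.12, 6.65 and 6.57 log2 units, and Prtn3 went from 11.9 ± 6.40 to 1605 ± 216 TPM. Ifitm6 and Pglyrp1, abundant in maturing neutrophils, reached 5176 ± 449 and 1676 ± 93.4 TPM (Pglyrp1 log2 4.43). The endothelial lipase gene Lipg rose from 0.1 to 115 ± 14.6 TPM (6.71, adjusted p = 6.64e-12). The stefin genes Cstdc6, Stfa2 and Stfa3 were higher by 8.49, 8.35 and 8.11, but these are near-identical copies whose reads can be exchanged, so the separate values are uncertain. Of the secondary and tertiary granule genes tested, 20 of 20 rose, and 20 did when adjusted over the list alone (list adjusted p = 4.44e-19, adjusted p = 0.109 with an estimated correlation). Of the primary granule genes, 14 of 15 rose, with 14 adjusted over the list alone (adjusted p = 0.0722 with an estimated correlation). In the list of mature neutrophil genes 22 of 24 rose and 1 fell, or 23 and 1 adjusted over the list alone (adjusted p = 0.0722 with an estimated correlation). Csf3r, the receptor of G-CSF, rose from 140.4 ± 37.8 to 735 ± 54.5 TPM (2.41, adjusted p = 1.25e-06), whereas Csf3 itself stayed below the expression filter. Of 14 genes of G-CSF and STAT3 signalling 11 rose and 1 fell (adjusted p = 0.0722 with an estimated correlation).

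Cell-cycle and glycolysis genes were also higher in T_I. Mki67, a marker of cycling cells, rose from 20.1 ± 3.87 to 124 ± 12.4 TPM (log2 2.59, adjusted p = 1.29e-06), and Ube2c, which acts at mitotic exit, rose from 23.8 ± 4.14 to 210.1 ± 10.0 TPM (3.10, adjusted p = 2.26e-09). Of the proliferation list 41 of 43 genes rose, with 41 adjusted over the list alone (adjusted p = 0.147 with an estimated correlation). The glycolytic enzymes Pkm and Pgk1 rose from 274 ± 19.6 to 1164 ± 88.6 TPM (2.08) and from 102 ± 6.70 to 339 ± 18.6 TPM (1.73, adjusted p = 1.52e-11). Of 19 glycolysis genes 16 rose and 2 fell, and this was the only list of the comparison still called with an estimated correlation (adjusted p = 0.0384).

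Lymphocyte and macrophage genes fell in T_I. Cr2, the complement receptor of mature B cells, fell from 249 ± 18.6 to 21.4 ± 5.61 TPM (log2 −3.52, adjusted p = 6.22e-10). Cd3e and Lck, of the T cell receptor complex and its signalling, fell from 164 ± 23.7 to 24.9 ± 3.06 TPM (−2.67) and from 266 to 35.8 ± 3.03 TPM (−2.86). Marco and Spic, a scavenger receptor of marginal zone macrophages and the factor that specifies red pulp macrophages, fell by 3.61 and 2.73 log2 units. Ciita, the master regulator of MHC class II, fell from 87.2 ± 2.65 to 13.9 ± 2.14 TPM (−2.58). Cd274, which encodes PD-L1, fell from 26.6 ± 1.23 to 5.54 ± 1.17 TPM (−2.09, adjusted p = 1.41e-09), and Pdcd1, which encodes PD-1, from 4.32 ± 0.546 to 0.957 ± 0.220 TPM (−1.44, adjusted p = 1.40e-06). Genes that fell numbered 28 of 29 in the B cell list, 34 of 35 in the T cell list, 28 of 29 in the interferon-gamma and MHC class II list and 17 of 18 in the dendritic cell list. With an estimated correlation these lists had adjusted p = 0.340, 0.218, 0.109 and 0.218 in camera. At the preset correlation camera gave them adjusted p = 1.4e-07, 1.17e-11, 3.37e-09 and 0.000424. The fry test, which does not compare a list with the other genes, gave adjusted p = 2.11e-08, 6.76e-10, 2.06e-11 and 2.50e-09. Of 19 red pulp genes 18 fell, 19 adjusted over the list alone (adjusted p = 0.416 with an estimated correlation), and 15 fell under median-of-ratios scaling. Of 37 type I interferon genes 30 fell and 2 rose (adjusted p = 0.608 with an estimated correlation).

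Haemoglobin transcripts were lower in T_I, where Hbb-bs, an adult beta globin of red cell precursors, fell from 2344 ± 661 to 199.6 ± 76.9 TPM (log2 −3.58, adjusted p = 1.64e-05). Globin copies are near-identical, so this value is uncertain. Nfe2, an erythroid and megakaryocyte transcription factor, rose from 18.6 ± 3.41 to 225 ± 14.9 TPM (3.54). This rise need not be erythroid. Nfe2 also fell alongside granule genes in N_GC against N_I (−1.08, adjusted p = 0.00152), where Hbb-bs did not pass (−0.30, adjusted p = 0.826). Of 38 erythroid genes 7 rose and 11 fell in T_I, or 5 and 11 adjusted over the list alone. The direction of the erythroid list depended on the scaling, as 16 rose and 7 fell with median of ratios. Arg1, an arginase made by suppressive myeloid cells, was 4.90 ± 7.13 TPM in T_I and 0.240 ± 0.416 in N_I with overlapping libraries (1.55, adjusted p = 0.0305). Its call was lost without N_I replicate 18 (adjusted p = 0.082) and without N_I replicate 92 (adjusted p = 0.0831), as well as without a filter (0.0573) and in a fit of only the libraries of the comparison (0.153), within a range of 0.00343 to 0.153 over the alternatives. The T_I mean of Arg1 rests on T_I replicate 12 (13.12 TPM, against 1.16 and 0.42), and without that library the gene was below the expression filter. limma called 11610 of 16635 genes between T_I and N_I, 2893 higher and 8717 lower, against 5094 higher and 5338 lower under median-of-ratios scaling. The limma p-values here and throughout rest on the spread between these samples, pooled over the 6 groups. The median SD over genes was 0.203 log2 units in T_GC and 0.122 to 0.145 in the other groups. Pooling can therefore understate the spread in comparisons with T_GC. The camera p-values compare the genes of a list with the other genes.

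**Figure D2:**
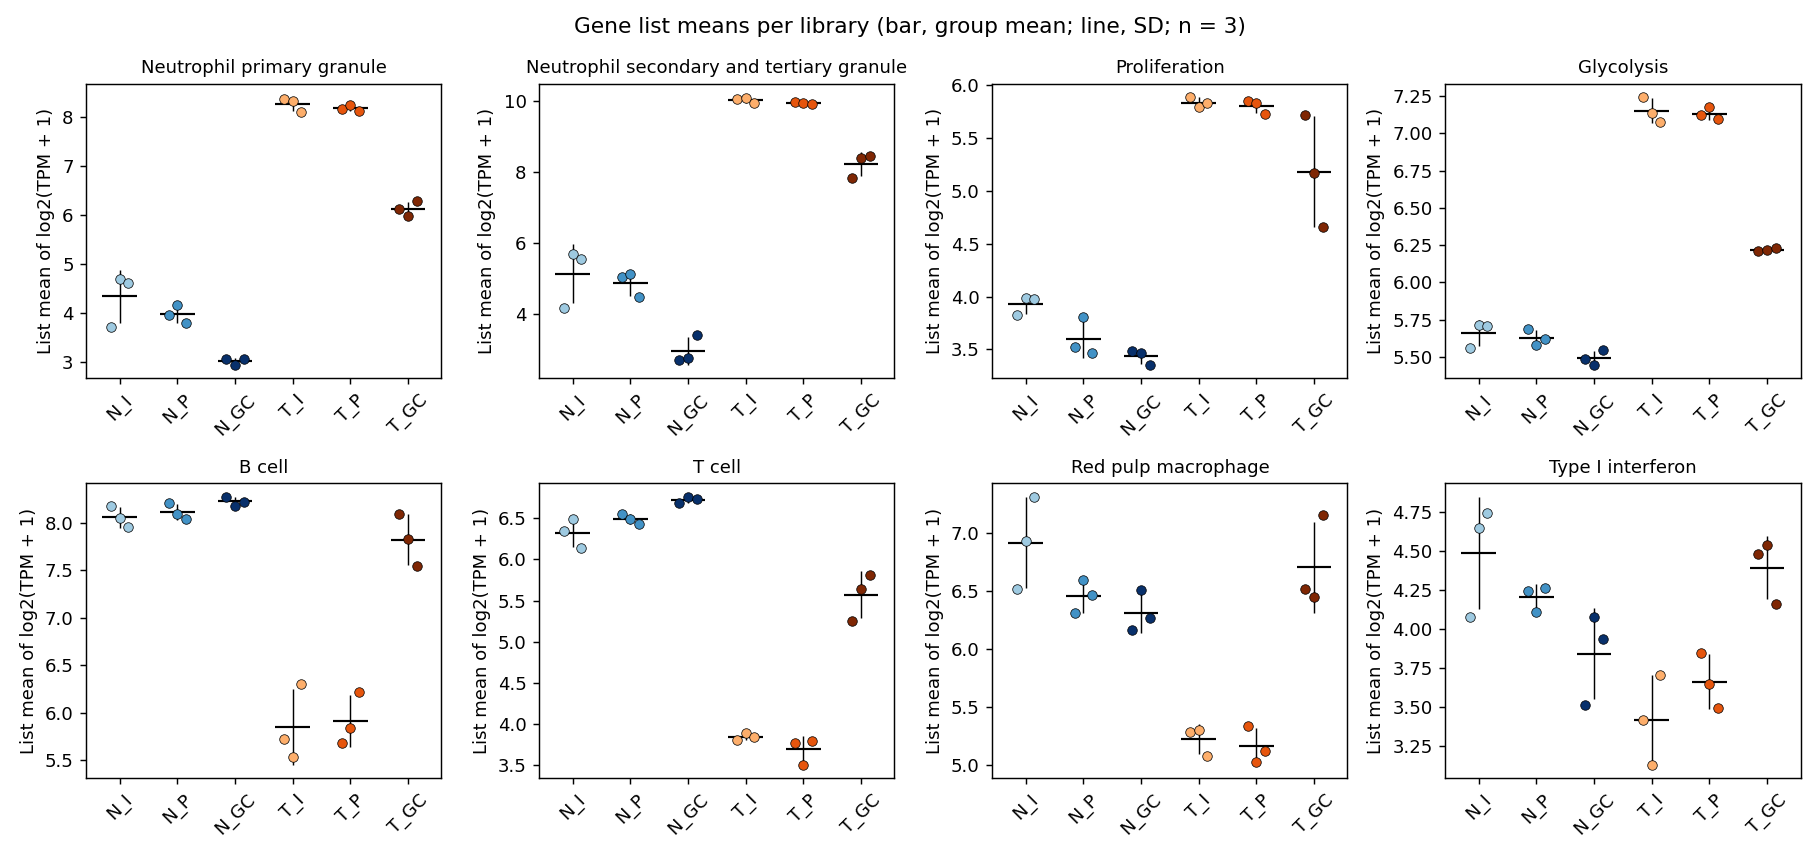
Mean log2(TPM + 1) of the genes of 8 lists in each library, 1 dot per library, with a bar at the group mean and a line for the SD. Granule, proliferation and glycolysis lists are highest in T_I and T_P, lymphoid and red pulp lists are lowest there, and T_GC lies between for granules, glycolysis and T cells and near the N groups for red pulp and type I interferon.

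The tumour response under code P was close to that under code I. In T_P, Prtn3 rose to 1530.1 ± 91.9 TPM from 6.13 ± 3.09 in N_P (log2 7.84, adjusted p = 2.60e-10), and Mpo, the myeloperoxidase of primary granules, rose from 10.3 ± 4.52 to 1409 ± 212.5 TPM (7.03). S100a9 rose from 2175 ± 467 to 102030 ± 4731 TPM (5.57, adjusted p = 5.06e-09). Cd3e fell from 193 ± 7.54 to 19.6 ± 2.95 TPM (−3.24, adjusted p = 1.33e-10) and Tcf7, a factor of naive T cells, by 3.29 log2 units. All 35 T cell genes, 28 of 29 B cell genes and 28 of 29 interferon-gamma and MHC class II genes fell, and 20 of 20 secondary and tertiary granule genes rose, with adjusted p = 0.186, 0.316, 0.110 and 0.110 with an estimated correlation. Between T_P and N_P limma called 11505 genes, 3138 higher and 8367 lower (5214 and 5332 under median-of-ratios scaling). Genes higher in both T_I and T_P numbered 2675, against 545.7 if calls were independent, and 7691 were lower in both, against 4384. The calls are not independent, because both comparisons take the spread of each gene from the same fit. The sum constraint of TPM also acts on both. Genes called in opposite directions numbered 2 and 5. Over all 16635 genes the fold changes of these comparisons, which share no library, had a correlation of 0.925 and a slope of 0.955, although genes are not independent replicates. Averaged over the 3 codes, 12888 genes were called, 3533 higher and 9355 lower (5719 and 6219 under median-of-ratios scaling). Those higher included Prtn3 (7.11, adjusted p = 6.67e-13), Elane (6.64) and the neutrophilic granule gene Ngp (6.36).

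Neutrophil granule genes also rose in tumour-bearing spleens under code GC, to lower levels. Ngp rose from 27.02 ± 14.4 TPM in N_GC to 6033 ± 878 in T_GC (log2 7.86, adjusted p = 7.12e-08), and Lcn2 and Ltf, iron-binding proteins of secondary granules, rose by 7.69 and 7.64. S100a9 rose from 422 ± 216 to 25505 ± 6364 TPM (5.99, adjusted p = 2.83e-08) and Csf3r from 49.5 ± 22.0 to 339 TPM (2.81, adjusted p = 1.56e-06). Mki67 rose from 9.66 ± 1.003 to 77.9 ± 42.9 TPM (2.75). T cell genes fell, with Cd3e down from 221 ± 6.24 to 93.3 ± 19.7 TPM (−1.26, adjusted p = 1.34e-05) and the CD8 beta chain gene Cd8b1 down from 111 ± 10.2 to 37.1 TPM (−1.64). Pdcd1 differed by −0.14 (adjusted p = 0.539). Cd274 fell from 27.3 ± 1.24 to 18.9 ± 2.46 TPM (−0.51, adjusted p = 0.00436). Of secondary and tertiary granule genes 20 of 20 rose, of proliferation genes 41 of 43 rose and of T cell genes 33 of 35 fell, 34 adjusted over the list alone, with adjusted p = 0.0551, 0.104 and 0.104 with an estimated correlation. Of 29 B cell genes 14 fell (adjusted p = 0.623 with an estimated correlation), and 14 of 37 type I interferon genes rose while 2 fell (adjusted p = 0.623 with an estimated correlation). The comparison of T_GC and N_GC gave 5532 genes in limma, 2383 higher and 3149 lower (2993 and 2226 under median-of-ratios scaling). A fit of only its own libraries gave 3399 genes.

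Between T_P and T_I, hardly any gene differed. S100a9 was 102030 ± 4731 TPM in T_P and 101870 ± 3342 in T_I (log2 0.00), and Cd3e differed by −0.33 (adjusted p = 0.805). Cd274 was 7.72 ± 0.451 in T_P and 5.54 ± 1.17 TPM in T_I (0.43, adjusted p = 0.650), and Pdcd1 was 1.55 ± 0.0961 and 0.957 ± 0.220 TPM (0.39, adjusted p = 0.775). limma called 2 of 16635 genes, while 1010 had an unadjusted p under 0.05. The microRNA gene Mir6236 (ENSMUSG00000098973) was at 102 ± 23.7 TPM in T_I and listed at 0 in T_P and every other group. The predicted gene Gm30085 fell from 5.64 ± 0.9996 to 0.697 ± 0.419 TPM (−1.98, adjusted p = 5.31e-05, 1.28e-05 to 0.251 over the alternatives). The number of genes was 4 without T_I replicate 8, 1 without T_I replicate 27 and 4 without T_P replicate 26. No member of any list passed over all genes. Adjusted over the list alone, 3 interferon-gamma and MHC class II genes, 2 heat-shock genes (Hspa8 and Hsph1), 1 type I interferon gene and 1 adipose gene were higher. The heat-shock and immediate-early list, called with the preset correlation (adjusted p = 0.00269), had adjusted p = 0.476 with an estimated correlation. The type I interferon list (adjusted p = 6.29e-06) and the T cell list (adjusted p = 0.000256), called by camera with the preset correlation, had adjusted p = 0.748 and 0.825 with an estimated correlation.

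Under code GC, neutrophil transcripts of tumour-bearing spleens fell relative to code I. S100a9 fell from 101870 ± 3342 TPM in T_I to 25505 ± 6364 in T_GC (log2 −2.03, adjusted p = 0.000254) and S100a8 by 2.09. Mpo fell from 1784 ± 279.9 to 154 ± 41.8 TPM (−3.55, adjusted p = 3.75e-06) and Lipg from 115 ± 14.6 to 6.53 ± 2.87 TPM (−4.00, adjusted p = 4.78e-09). Prok2, a neutrophil-derived secreted peptide, fell from 87.9 ± 33.9 to 5.47 TPM (−3.76), and Csf3r from 735 ± 54.5 to 339 TPM (−1.14, adjusted p = 0.00187). Of primary granule genes 15 of 15 fell, 15 adjusted over the list alone (adjusted p = 0.0479 with an estimated correlation), as did 19 of 20 secondary and tertiary granule genes (adjusted p = 0.190 with an estimated correlation). Of 24 mature neutrophil genes 22 fell and 1 rose (adjusted p = 0.0854 with an estimated correlation). Pkm fell from 1164 ± 88.6 to 457 TPM (−1.34, adjusted p = 2.46e-09) and Pgk1 from 339 ± 18.6 to 157 ± 3.66 TPM (−1.10). Of 19 glycolysis genes 16 fell and 1 rose, and this list together with the primary granule list was called with an estimated correlation (glycolysis adjusted p = 0.0190). Of 43 proliferation genes 30 fell, among them Ube2c from 210.1 ± 10.0 to 93.0 ± 31.1 TPM (−1.22, adjusted p = 5.73e-05), while the list had adjusted p = 0.307 with an estimated correlation and 41 fell under median-of-ratios scaling.

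Mki67 was 77.9 ± 42.9 TPM in T_GC and 124 ± 12.4 in T_I, with overlapping libraries (log2 −0.80, adjusted p = 0.0244, 0.000336 to 0.137 over the alternatives). The call on Mki67 was lost in 6 of 14 alternatives. Among these were the omission of T_GC replicate 21 (adjusted p = 0.0652), T_GC replicate 37 (adjusted p = 0.137) or T_I replicate 8 (adjusted p = 0.0746).

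Lymphoid, dendritic and macrophage transcripts rose in T_GC relative to T_I. Cr2 rose from 21.4 ± 5.61 to 158 ± 17.2 TPM (log2 2.86, adjusted p = 2.69e-08) and Cxcr5, the receptor that leads B cells to follicles, from 18.7 to 85.6 ± 1.70 TPM (2.15). Cd3e rose from 24.9 ± 3.06 to 93.3 ± 19.7 TPM (1.85, adjusted p = 1.33e-07) and Ccr7, the homing receptor of naive T cells, from 18.7 ± 2.64 to 89.7 ± 5.98 TPM (2.21). Irf8, a factor of dendritic cells and monocytes, rose from 62.1 ± 6.54 to 184 ± 14.7 TPM (1.55), and Spic rose by 2.21 and Marco by 2.39. Cd274 rose from 5.54 ± 1.17 to 18.9 ± 2.46 TPM (1.62, adjusted p = 7.15e-08) and Pdcd1 from 0.957 ± 0.220 to 3.40 ± 0.831 TPM (1.16, adjusted p = 2.35e-05). Genes that rose numbered 29 of 29 in the B cell list, 34 of 35 in the T cell list, 17 of 18 in the dendritic cell list and 28 of 29 in the interferon-gamma and MHC class II list, with adjusted p = 0.307, 0.274, 0.247 and 0.105 with an estimated correlation. Of 19 red pulp genes 17 rose, 18 adjusted over the list alone and 13 under median-of-ratios scaling (adjusted p = 0.473 with an estimated correlation). Of 37 type I interferon genes 31 rose, or 20 under that scaling (adjusted p = 0.544 with an estimated correlation). The comparison of T_GC and T_I gave 10224 genes in limma, 8109 higher and 2115 lower, which became 4135 and 4449 under median-of-ratios scaling. After removal of the genes of the 3 neutrophil lists from the total, an alternative chosen after the data had been seen, 8644 genes were called, 5222 higher and 3422 lower.

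**Figure D3:**
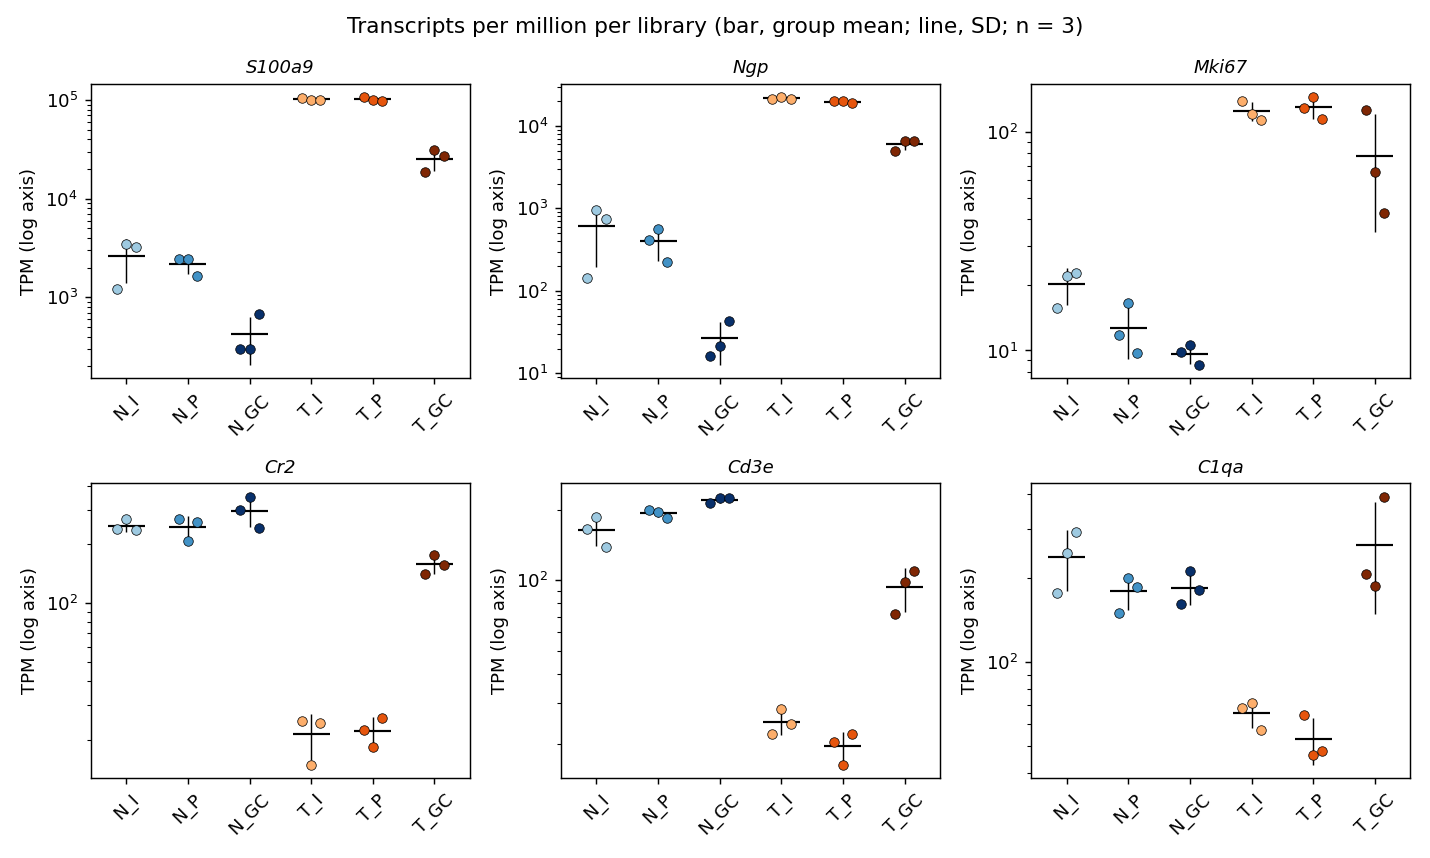
TPM of S100a9, Ngp, Mki67, Cr2, Cd3e and C1qa in each library on a log axis, grouped by code and tumour status, 1 dot per library. S100a9 and Ngp are high in all T groups and lower in T_GC than in T_I or T_P, and Cr2, Cd3e and C1qa are lowest in T_I and T_P.

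T_GC was also compared with T_P, a comparison that shares its T_GC libraries with the previous one. Prok2 fell from 138.5 ± 29.4 TPM in T_P to 5.47 in T_GC (log2 −4.47), and Prg2 and Epx, granule proteins of eosinophils, fell from 521 ± 154.5 to 44.1 ± 11.4 TPM (−3.52) and from 60.4 ± 20.4 to 4.96 ± 3.54 TPM (−3.46). Cd200, an immunoregulatory ligand of B cells, rose from 5.04 to 34.6 ± 9.24 TPM (2.53), and Cd3e by 2.18 (adjusted p = 3.48e-08). All 35 T cell genes and all 29 B cell genes rose (adjusted p = 0.222 and 0.273 with an estimated correlation), 15 of 15 primary granule genes fell (adjusted p = 0.0523 with an estimated correlation), and of 19 glycolysis genes 16 fell and 1 rose (adjusted p = 0.0208 with an estimated correlation). In total 10284 genes passed in limma, 8173 higher and 2111 lower, or 4281 and 4415 under median-of-ratios scaling. To avoid libraries shared between comparisons, genes that answered to the tumour under 1 code by at least 1 log2 unit, in a fit of only the 6 libraries of that code, were tested between the other codes. These strongly changed sets are smaller than the numbers given above. The set higher in T_P than N_P had a median of −0.86 in T_GC against T_I, where 1311 of 1673 fell and 12 rose (unadjusted camera p = 1.69e-06 with an estimated correlation). Of the set of 3335 genes lower in T_P than N_P by that rule, 2991 rose and 1 fell (median 1.05, unadjusted camera p = 0.000306 with an estimated correlation), while the median of all genes was 0.38. Likewise, of the set of 1478 genes higher in T_I than N_I, 1207 fell in T_GC against T_P (median −0.92), and of the set of 3466 lower genes 3105 rose (1.07). The set of 893 genes higher in T_GC than N_GC had a median of −0.012 in T_P against T_I (unadjusted camera p = 0.874 with an estimated correlation). The set of 303 genes lower in T_GC than N_GC had a median of −0.088 there (unadjusted camera p = 0.00282, p = 0.312 with an estimated correlation). Without a tumour, in tests chosen after the data had been seen, the sets higher with the tumour under codes P and I were lower in N_GC, whereas the corresponding lower sets did not pass with an estimated correlation (unadjusted camera p = 0.0852 and 0.283). Of the set higher in T_P, 264 fell and 0 rose in N_GC against N_I (median −0.29, unadjusted camera p = 0.000223 with an estimated correlation), and of the set higher in T_I, 88 fell and 2 rose in N_GC against N_P (−0.15, unadjusted camera p = 0.00142 with an estimated correlation).

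Whether code GC acted differently in tumour-bearing and WT spleens was tested as an interaction of T_GC, T_I, N_GC and N_I. Ifit3, an antiviral gene induced by type I interferon, was 16.7 ± 7.35 TPM in N_I, 6.35 ± 2.29 in N_GC, 1.69 ± 0.859 in T_I and 11.6 ± 2.18 in T_GC (log2 difference 3.48, adjusted p = 5.18e-05). Spic had an interaction of 2.88 (adjusted p = 1.62e-06), Cd274 of 1.58 (adjusted p = 1.10e-05), Pdcd1 of 1.30 (adjusted p = 0.000463) and Cd3e of 1.41 (adjusted p = 0.000131). Lipg had −3.93 (adjusted p = 7.79e-07), and Ggt1, a glutathione-degrading enzyme, was 54.3 ± 7.29 TPM in T_I and between 4.62 and 5.70 in the other groups of this interaction (−3.36). S100a9 (0.58, adjusted p = 0.401), Csf3r (0.40, adjusted p = 0.422) and Mki67 (0.16, adjusted p = 0.775) did not pass. Positive interactions were found for 35 of 37 type I interferon genes, 19 of 19 red pulp genes and 18 of 18 dendritic cell genes, with adjusted p = 0.357, 0.311 and 0.125 with an estimated correlation, and 26 interferon genes passed under median-of-ratios scaling. Lists still called with an estimated correlation were checkpoint receptors and ligands, where 20 of 23 genes were positive and 21 adjusted over the list alone (adjusted p = 0.0171), and glycolysis, where 14 of 19 were negative (adjusted p = 0.0131). limma called 6717 genes, 5564 positive and 1153 negative (2544 and 2882 under median-of-ratios scaling). This number alone does not establish a dependence on N libraries, because splits that exchanged only N libraries and left the gap between T_GC and T_I in place gave up to 8862.

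The interaction of code P with the tumour involved 3 genes in limma, all negative, while 1146 had an unadjusted p under 0.05. Ahsa2, a co-chaperone of HSP90, was 27.6 ± 3.94 TPM in N_I, 67.2 ± 7.51 in N_P, 23.4 ± 3.19 in T_I and 25.2 ± 1.05 in T_P (log2 difference −1.15, adjusted p = 0.0469, 0.0267 to 0.215 over the alternatives). Its call was lost in 13 of 20 alternatives. Among these were the omission of N_I replicate 92 (adjusted p = 0.0799), N_P replicate 17 (0.215) or 29 (0.164), T_I replicate 8 (0.163) or 12 (0.213), and T_P replicate 26 (0.161), 39 (0.181) or 43 (0.0957). Gm30085 (−1.98, adjusted p = 0.00450, 0.000504 to 0.322 over the alternatives) was lost in 4 of 19 alternatives, among them without T_I replicate 8 (adjusted p = 0.0542) or 12 (adjusted p = 0.0507). Mir6236 was listed at 0 outside T_I. The number of genes was 11 without N_I replicate 18, and no gene passed without T_I replicate 8 or without T_I replicate 12, where Mir6236 was below the expression filter. Regrouping the libraries did not exclude chance, with a highest other split of 34 genes.

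Heat-shock genes rose in N_P relative to N_I. Hsph1, a nucleotide exchange factor of HSP70, rose from 51.0 ± 6.94 to 198 ± 39.8 TPM (log2 1.92, adjusted p = 0.00150). The co-chaperones Dnaja1 and Stip1 rose from 184 ± 27.4 to 541 ± 72.6 TPM (1.56, adjusted p = 0.000216) and from 64.3 ± 8.39 to 183 ± 30.7 TPM (1.49). The constitutive chaperone gene Hspa8 rose from 841 ± 126 to 1879 ± 151 TPM (1.17), and Hsp90aa1, the inducible HSP90, from 150.02 ± 7.03 to 306 ± 40.8 TPM (1.02, adjusted p = 0.00366). Hspa1b, an inducible HSP70 gene with a near-identical copy and therefore an uncertain value, rose from 2.14 ± 0.718 to 21.7 ± 6.82 TPM (2.83, adjusted p = 0.0308, 0.0175 to 0.129 over the alternatives). The call on Hspa1b was lost in 7 of 14 alternatives. Among these were the omission of N_I replicate 92 (adjusted p = 0.0726) or 96 (0.118) and of N_P replicate 17 (0.125), 29 (0.129) or 38 (0.0535). Of 21 heat-shock and immediate-early genes 5 rose, 5 adjusted over the list alone (adjusted p = 0.162 with an estimated correlation). Hbb-bs was 934 ± 458 against 2344 ± 661 TPM (−1.39, adjusted p = 0.242). Adjusted over the list alone, 22 of 38 erythroid genes were lower and 1 higher, although none passed over all genes (list adjusted p = 1.34e-10, adjusted p = 0.558 with an estimated correlation). limma called 95 genes, 52 higher and 43 lower (78 and 26 under median-of-ratios scaling), and a fit of only the libraries of the comparison called 2, none of them a heat-shock gene named here, while array weights by tumour status gave 204. The number was 250 without N_I replicate 18, 34 without N_I replicate 92, 27 without N_I replicate 96, 22 without N_P replicate 17, 22 without N_P replicate 29 and 37 without N_P replicate 38.

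**Figure D4:**
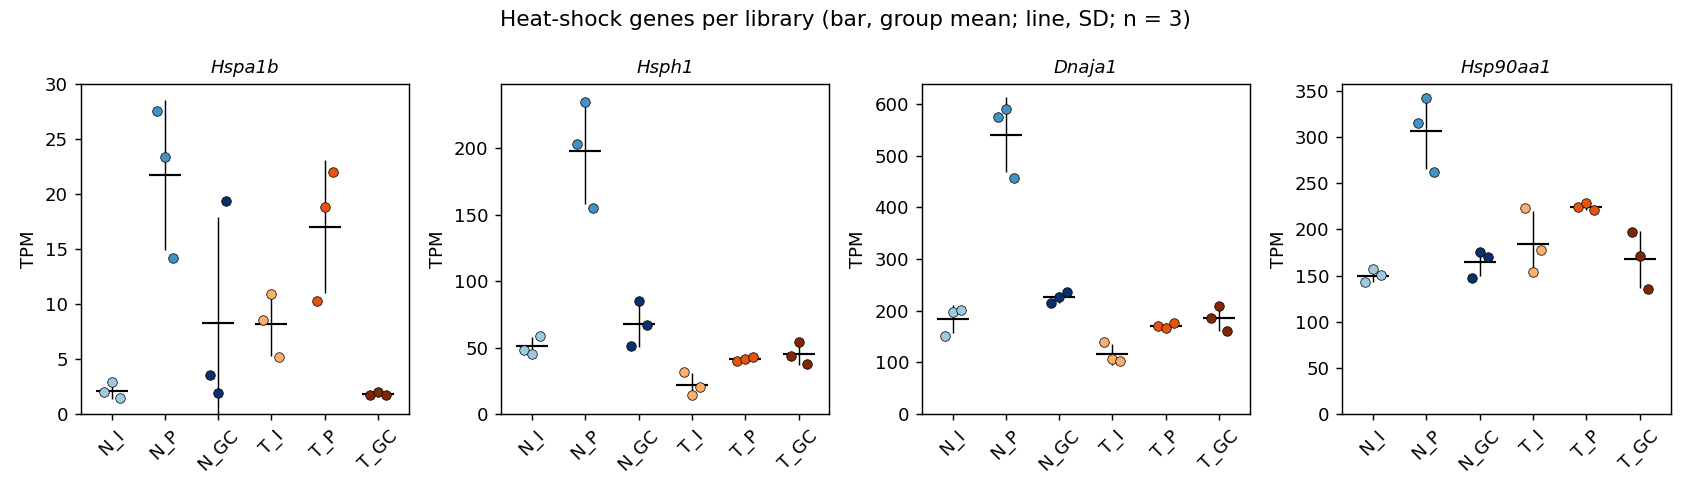
TPM of Hspa1b, Hsph1, Dnaja1 and Hsp90aa1 in each library on a linear axis, 1 dot per library, by group. The mean of each gene is highest in N_P, but for Hspa1b the N_P libraries overlap with those of T_P and with 1 library of N_GC.

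Granule genes fell in N_GC relative to N_I. Ngp fell from 618 ± 423 to 27.02 ± 14.4 TPM (log2 −4.19, adjusted p = 0.00178), Lrg1, an acute-phase glycoprotein also stored in neutrophil granules, from 18.3 ± 6.45 to 1.16 ± 0.499 TPM (−3.13, adjusted p = 4.88e-05), and S100a9 from 2641 ± 1247 to 422 ± 216 TPM (−2.61). Csf3r fell from 140.4 ± 37.8 to 49.5 ± 22.0 TPM (−1.54, adjusted p = 0.00595). N_I replicate 18 had less of these transcripts than the other N_I libraries (S100a9 1204 TPM, against 3447 and 3271), and the fold change of Ngp ran from −5.04 to −3.68 over the alternatives. Of 20 secondary and tertiary granule genes 18 fell, 20 adjusted over the list alone (list adjusted p = 2.13e-32, adjusted p = 0.0524 with an estimated correlation), as did 13 of 24 mature neutrophil genes (adjusted p = 0.0524 with an estimated correlation) and 9 of 15 primary granule genes (adjusted p = 0.0650 with an estimated correlation). Cd247, the zeta chain of the T cell receptor, rose from 96.8 ± 14.6 to 135.5 ± 3.39 TPM (0.49, adjusted p = 0.0211, 0.0107 to 0.156 over the alternatives) as the only T cell gene over all genes, and 20 of 35 did adjusted over the list alone (adjusted p = 0.114 with an estimated correlation). The call on Cd247 was lost in 5 of 14 alternatives, among them the omission of N_GC replicate 11, 36 or 94 or of N_I replicate 96. Cd3e (0.44, adjusted p = 0.147) and Mki67 (−0.97, adjusted p = 0.0960) did not pass. Of 43 proliferation genes 5 fell, 15 adjusted over the list alone (adjusted p = 0.180 with an estimated correlation), among them Ube2c (−1.09, adjusted p = 0.00577). Of 37 type I interferon genes 6 fell, 22 adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). limma called 458 genes, 75 higher and 383 lower (45 and 411 under median-of-ratios scaling), and a fit of only the libraries of the comparison called 2, in which Ngp had adjusted p = 0.134. The number was 220 without N_GC replicate 11, 212 without N_GC replicate 36, 281 without N_GC replicate 94, 228 without N_I replicate 92 and 145 without N_I replicate 96.

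Relative to N_P, spleens of N_GC showed lower granule and heat-shock transcripts. Lrg1 fell from 31.1 ± 7.58 to 1.16 ± 0.499 TPM (log2 −3.89, adjusted p = 3.85e-06), Ngp from 401 ± 171 to 27.02 ± 14.4 TPM (−3.86, adjusted p = 0.00315) and S100a9 from 2175 ± 467 to 422 ± 216 TPM (−2.45, adjusted p = 0.00450). The co-chaperone gene Dnajb1 fell from 70.2 to 35.1 TPM (−0.97, adjusted p = 0.00142) and Hspa8 by 0.92 (adjusted p = 0.00411). Of 20 secondary and tertiary granule genes 12 fell, 19 adjusted over the list alone (adjusted p = 0.0544 with an estimated correlation), and of 21 heat-shock and immediate-early genes 3 fell, 7 adjusted over the list alone (adjusted p = 0.0544 with an estimated correlation). limma called 195 genes, 71 higher and 124 lower (38 and 181 under median-of-ratios scaling), a fit of only the libraries of the comparison called 7, and array weights by tumour status gave 442. The number was 69 without N_GC replicate 11, 91 without N_GC replicate 36, 88 without N_P replicate 17, 114 without N_P replicate 29 and 99 without N_P replicate 38.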

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

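The regroupings of libraries were fixed before the results, and the tests of which libraries those splits kept together were chosen after the result was seen.

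The interaction of code P with tumour status called 3 genes, Mir6236, Gm30085 and Ahsa2. Among 100 regroupings 6 gave at least 3 genes, with a highest of 34 in another split, so the number could have arisen by chance from how the libraries are grouped. Without T_I replicate 8 or T_I replicate 12 none of the 3 was called. Without T_I replicate 27, where Mir6236 was below the filter, the other 2 remained. Mir6236 was at 102 ± 23.7 TPM in T_I (n = 3) and listed at 0 in all other groups. As T_GC, N_I and N_GC were at 0 too, the difference sets T_I apart and is not particular to code P. Whether it reflects an animal-level difference, the library preparation or a different annotation or quantification of those libraries is open.

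The interaction of code GC with tumour status called 6717 genes, among them Ifit3 (log2 difference 3.48), Spic (2.88) and Cd274 (1.58). Among 100 regroupings 10 gave at least 6717, with a highest of 8862 in another split. Each of the other 9 splits kept the T_I libraries apart from the T_GC libraries and exchanged only N libraries. The large number in those splits therefore points to sample structure, the wide gap between T_I and T_GC, which an exchange among N libraries leaves in place by construction. The regrouping thus could not test this interaction apart from that gap, and chance is neither excluded nor shown by it. Genes that differed numbered 10224 between T_GC and T_I and 458 between N_GC and N_I. Ifit3 was higher by 2.26 in T_GC than in T_I (adjusted p = 3.03e-05), while its difference of −1.22 in N_GC against N_I did not pass (adjusted p = 0.353).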

How the results depend on the processing

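Tests with TPM recomputed without neutrophil list genes were chosen after the result was seen, and all others before. No paired analysis was possible because no replicate number is shared between groups.

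Of 18738 alternative values of the genes reported, 18062 kept the call and its direction, 612 were weaker, 56 stronger and 8 reversed. The causes of the moves below were not tested. For T_P against T_I the number of genes, 2 as reported, was 1 with a pseudocount of 0.1, 4 without a filter and 1 with a filter of 5 TPM, and 1 to 4 when a library was left out. For the interaction of code P it was 1 with a pseudocount of 0.1, 1 in a fit of only its own libraries and 0 to 11 when a library was left out. A fit of only the own libraries gave 3399 genes for T_GC against N_GC, 2 for N_P against N_I, 2 for N_GC against N_I and 7 for N_GC against N_P. Residual degrees of freedom are few in such fits. Array weights by tumour status gave 204 genes for N_P against N_I and 442 for N_GC against N_P. Such weights are common to all T libraries, so they make no allowance for the wider spread of T_GC. Leaving out a library gave 22 to 250 genes for N_P against N_I, 145 to 686 for N_GC against N_I and 69 to 138 for N_GC against N_P.

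With an estimated correlation the number of lists called by camera was 0 for T against N averaged over codes, 1 for T_I against N_I, 0 for T_P against N_P, 0 for T_GC against N_GC, 0 for T_P against T_I, 2 for T_GC against T_I, 1 for T_GC against T_P, 0 for N_P against N_I, 0 for N_GC against N_I, 0 for N_GC against N_P, 0 for the interaction of code P and 2 for the interaction of code GC. The lists kept were glycolysis in all 4 comparisons with any, primary granules in T_GC against T_I and checkpoint genes in the interaction of code GC. For the interaction of code P, 10 to 17 lists were called when a library was left out, 17 of them without N_I replicate 18.

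Median-of-ratios scaling reversed single genes near 0. These were Nkg7 (0.015) and Jak2 (0.10) averaged over codes, Jak2 (0.027) and Pfkp (0.059) in T_I against N_I, Jak2 (0.087) in T_P against N_P, Jak2 (−0.033) in T_GC against T_I, and Jak2 (−0.049) and Cdt1 (−0.19) in T_GC against T_P. By construction that scaling moves all genes of a library alike. The camera direction of B cell genes in the interaction of code P, −1 with all libraries, became 1 without T_I replicate 27 (adjusted p = 0.00974). The direction of erythroid genes in T_P against T_I, −1 with all libraries, became 1 without T_P replicate 43 (adjusted p = 0.00625). Genes higher in T_GC than N_GC had a median of −0.0346 to 0.0238 in T_P against T_I when a library was left out, on either side of 0, and the opposite direction passed the preset correlation only without T_P replicate 43 (0.0173). Genes lower in T_GC had −0.152 to −0.00784. Their call with the preset correlation was lost without T_P replicate 39 and, with all libraries, under an estimated correlation (p = 0.312).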

Other observations

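The comparisons, the list tests and the regroupings of libraries were fixed beforehand, the removal of neutrophil list genes was added after the data but before its own outcome had been seen, and the other tests of technical explanations were chosen after the result was seen.

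Single genes of eosinophils and progenitors rose with the tumour and were lower in T_GC than in T_I, but the members of their lists moved both ways in T_GC. Prg2, the major basic protein of eosinophils, rose from 6.83 ± 3.62 TPM in N_I to 490.5 ± 22.5 in T_I (log2 6.11, adjusted p = 9.95e-10, n = 3) and was 44.1 ± 11.4 in T_GC (−3.48 against T_I, adjusted p = 8.33e-07). Siglecf, a lectin of eosinophils, rose by 2.54 and fell by 1.85 in T_GC, while Cma1, a mast cell chymase, moved the other way (−1.92 and 1.26). In T_GC against T_I the mast cell, basophil and eosinophil list had 6 genes higher and 5 lower (median −0.21), and the stem and progenitor list 6 higher and 8 lower (median 0.04, or −0.29 under median-of-ratios scaling), with adjusted p = 0.00385 and 0.0107 at the preset correlation and adjusted p = 0.307 for both with an estimated correlation. Prom1 and Erg, genes of haematopoietic progenitors, rose from 0.857 ± 0.454 to 37.95 ± 3.78 TPM (4.42) and from 1.74 ± 0.934 to 30.8 ± 3.09 TPM (3.60), and Prom1 fell by 2.31 in T_GC. Between T_I and N_I 10 of 18 mast cell, basophil and eosinophil genes rose and 5 fell, and 13 of 21 stem and progenitor genes rose and 5 fell, with adjusted p = 0.172 and 0.147 with an estimated correlation. The platelet adhesion gene Selp rose from 0.54 ± 0.221 to 12.8 ± 0.634 TPM (3.17) while the integrin gene Itgb3 fell by 0.96, and of 20 megakaryocyte genes 4 rose and 6 fell. Of 20 myeloid suppressor genes 14 rose and 3 fell (adjusted p = 0.0722 with an estimated correlation), of 16 monocyte genes 9 rose and 7 fell (adjusted p = 0.416 with an estimated correlation), and of 17 inflammatory cytokine genes 9 rose and 6 fell (adjusted p = 0.282 with an estimated correlation).

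Cholesterol synthesis, stromal and effector lymphocyte genes also differed between T_I and N_I. Fdps, an enzyme of the mevalonate pathway, rose from 25.3 ± 1.96 to 98.5 ± 24.6 TPM (log2 1.89, n = 3) and was 26.03 TPM in T_GC (−1.85 against T_I, adjusted p = 3.29e-08). Of 20 cholesterol genes 8 rose and 5 fell in T_I, or 14 and 3 under median-of-ratios scaling (adjusted p = 0.416 with an estimated correlation). The endothelial genes Pecam1 and Stab2 fell by 1.96 log2 units and from 26.8 ± 2.06 to 4.45 ± 0.315 TPM (−2.35), with 11 of 14 stromal and endothelial genes lower and 1 higher. Jchain, the joining chain of secreted antibodies, fell from 912 to 267 TPM (−1.76), and of 24 plasma cell genes 16 fell and 5 rose. Prf1, the pore-forming protein of killer cells, fell from 27.4 ± 5.36 to 3.84 ± 0.223 TPM (−2.54). Genes that fell numbered 19 of 23 cytotoxic effector genes, 13 of 16 NK cell genes, 14 of 16 regulatory T cell genes, 19 of 23 checkpoint genes and 5 of 5 marginal zone macrophage genes, with adjusted p = 0.387, 0.416, 0.373, 0.0793 and 0.340 with an estimated correlation.

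Epithelial and adipose genes, which could mark other tissue, did not all move in the same direction. Epcam, an epithelial adhesion gene, fell by 1.02 log2 units in T_I against N_I (n = 3), and of 7 epithelial genes that passed the filter 3 rose and 2 fell. Of 4 adipose genes 3 fell and 1 rose, with Pparg down by 2.07. Mitochondrially encoded genes do not mark another tissue. Of these, 10 of 15 fell and 1 rose, or 5 and 2 under median-of-ratios scaling.

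The lower neutrophil and higher lymphoid transcripts of T_GC relative to T_I were put against 2 technical readings. If a few abundant genes only took up the total, removal of the neutrophil list genes would bring the lymphoid genes to about 0, but the median of B and T cell genes stayed at 1.62. This outcome was largely fixed, because the removed genes held 23.2% of TPM in T_I and 6.02% in T_GC, which allows only a small shift. The listed genes thus cannot account for the lymphoid rise, but removal of other neutrophil transcripts was not tested. Median-of-ratios scaling takes out a shift common to all genes of a library. Under it 29 of 29 B cell genes stayed higher (median 1.57), while 33 T cell genes were higher and 1 lower (median 1.40). These values argue against a dilution common to all genes as the source of the lymphoid rise. If neutrophil transcripts alone had a lower share and other cells kept their proportions, the other lists would move alike, but their medians spanned 2.22 log2 units, from −0.22 for monocyte genes to the highest for B cell genes. This spread argues against unchanged proportions among the transcripts of these lists. It does not decide the proportions of cells, because members moved both ways within the monocyte list (6 higher and 6 lower). Whether list members are also transcribed in neutrophils was not tested.

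The higher heat-shock genes of N_P could come from tissue handling, which would be likely to raise immediate-early genes as well. Their median was 0.0144 and none of 16 passed, against 1.92 for the heat-shock genes, which argues against handling stress of that kind. Single genes differed, as Jun was 10.07 to 14.54 TPM in N_P and 7.59 to 8.57 in N_I. Fos went the other way, with 4.02 to 7.64 and 7.53 to 11.03 TPM. Handling that leaves only heat-shock transcripts high is not excluded. A batch shared by the N_P libraries cannot be told apart from code P, as the heat-shock genes were also lower by a median of −1.54 in N_GC than in N_P. Of these 5 genes 3 passed in that comparison. Hspa1b in N_GC replicate 94 (19.31 TPM) lay within the N_P range of 14.18 to 27.51 TPM. An effect of code P in both tumour states stays open and cannot be told apart from one in WT mice, with a median of 0.62 in T_P against T_I. There none passed over all genes, while Hspa8 and Hsph1 did when adjusted over the list alone.

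Xist, the RNA that silences 1 X chromosome in female cells, was 13.6 TPM in T_GC replicate 21, against 174.6 and 94.96 in the other T_GC libraries. A male sample would likely carry Y-linked transcripts, but these summed to 0.03 TPM, which argues against a mislabelled animal. Tumour cells without Xist would raise epithelial genes, whose mean differed by −0.11, against this reading as well. Genes that escape X inactivation had a median deviation of −0.48 from the other T_GC libraries, as low or lower in 0.02% of 10000 random sets of 4 genes of like level. Kdm5c (30.78 TPM) was below every other library. Kdm6a (24.09), Eif2s3x (61.95) and Ddx3x (121.1), however, were near their values in T_I replicate 12 (20.44, 62.03 and 118.8). Xist was 71.09 TPM there, so fewer cells with an inactive X chromosome is only a candidate explanation, which these values do not decide.

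Replicates of T_GC differed among themselves. Mki67 was 125.6 TPM in T_GC replicate 10, 65.5 in replicate 21 and 42.5 in replicate 37, and the proliferation list had means of 5.71, 5.17 and 4.66 in that order. On the second principal component these libraries lay at −63.0, −35.7 and −18.8. Arg1 was 13.1 TPM in T_I replicate 12 and 1.16 and 0.42 in the other T_I libraries.

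Regrouping of the libraries gave as many genes as reported in 1 of 100 splits for T against N averaged over codes, the real one, with 12888 genes against a highest other of 11970. Which libraries that other split kept together was not examined, so the reason for its large number is open. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Every other such split also puts libraries of both real groups on each side. A gap between the groups then enters the pooled spread, which lowers the number called in those splits by construction. The real number and the highest other were 11610 and 2 for T_I against N_I, 11505 and 1 for T_P against N_P, 5532 and 2 for T_GC against N_GC, 10224 and 38 for T_GC against T_I, 10284 and 2 for T_GC against T_P, 95 and 2 for N_P against N_I, 458 and 2 for N_GC against N_I, and 195 and 2 for N_GC against N_P, so the real split was 1 of 10 in each. For T_P against T_I 3 splits gave at least the 2 genes of the real one, with a highest other of 3, and grouping by chance cannot be excluded.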
